A study of Pistacia chinensis with 8 samples.

How the data were processed

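Small RNA was sequenced from inflorescence buds of Chinese pistache (Pistacia chinensis), a tree in which most plants carry flowers of a single sex and some carry flowers of more than 1 kind. Buds came from 4 sex types (female, male, monoecious female and monoecious bisexual) at 2 developmental stages, named B and C in the labels, which gave 8 libraries with 1 library per sex type and stage. Per the labels' protocols, libraries were prepared from 3 micrograms of total RNA with the NEBNext small RNA kit after extraction with a plant RNA kit. The labels give strain C1 for female, X1 for male and T2 for both monoecious bud types.

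The deposited table held raw read counts for 471 miRNA rows, of which 385 carried miRBase-style names from 67 families and 51 species prefixes and 86 were predicted miRNAs numbered by the authors. A second set of columns held TPM values made by the authors, which equalled each count divided by its column total and multiplied by 1000000, within 4.29e-05, so no length term entered them. Per the submitters' processing notes, CASAVA 1.8 and Bowtie were used. The genome build, the miRBase release and the mismatches allowed are not given in the sources used here. No sequences or coordinates of the rows were used here, so rows are named as in the file. Only the counts were analysed further, and 0 count columns were left unmatched to a sample.

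Reads were counted on more than 1 row, as in aly-miR165a-3p and ath-miR165a-3p, which had equal counts of 34 to 593 reads in every library. Of the 471 rows, 84 repeated the counts of another row exactly, whatever its family. Rows with few reads can match without sharing reads, so this count is not a count of shared reads. For example, bra-miR403-5p and sly-miR168a-3p each held 1 read in bisexual buds at stage C and 0 elsewhere. Rows of a family whose counts lay within 5% or 2 reads of each other in every library were treated as near-identical, which joined 195 rows into 63 groups and left 339 groups in all. Counts of single rows of a family are therefore not independent, and arm names are uncertain where a 5p and a 3p name hold the same reads. Families, defined by the number in the name, were also tested after summing the reads of their rows, which counts shared reads more than once.

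Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM normalization) on the 248 rows with at least 10 reads in at least 2 libraries, in an additive model of stage and sex type. With 1 library per group the model left 3 residual degrees of freedom, and the spread it used was the sex type by stage interaction (common dispersion 0.268). P-values measure that spread and not a spread between replicate trees, and the labels do not say whether the libraries came from separate trees or pools. The stage effect was also allowed to differ between flower classes in a model with 2 residual degrees of freedom. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were computed as the absolute log2 fold change divided by the square root of F. Levels are TMM-normalised CPM. Levels of a stage are given as the mean ± SD over 4 libraries, 1 of each sex type. Ratios of 2 libraries carry exact conditional binomial 95% intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules. Where a library held 0 reads, a floor of 3 reads per library was used for a lower bound of the fold.

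Male against female buds compared strain X1 with C1, and monoecious against dioecious buds compared T2 with C1 and X1, so sex type and strain were confounded there. Bisexual and monoecious female buds both came from T2. The model, the alternatives, the lists of families and the rules for naming miRNAs were fixed before the data were examined, while the rules picked the named miRNAs from these data. Named were the 5 rows with most reads, up to 10 called rows per direction and comparison with the largest changes (the 5 with the smallest p where none passed), and up to 4 families with most reads from each fixed list. The lists were phase change and flowering time, floral organ and meristem regulators, auxin, nutrient and copper, silencing machinery, NBS-LRR and phasiRNA, MYB, anther and pollen, predicted miRNAs, and non-plant names. Alternatives were RLE factors, total counts alone, no filter, a minimum of 50 reads, DESeq2 1.42.0, identical rows kept once, family sums, reduced models and leaving out each library. Alternatives added after the data were seen were near-identical rows kept once, the most abundant row per family, thinning to the smallest library and leaving out both bisexual libraries.

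The procedure was tested on simulated data with 248 rows, 50 of them changed, in 20 simulations each. For the stage comparison it recovered 65.7% of rows changed 4-fold and 98.8% of rows changed 16-fold. For male against female it recovered 25.6% and 87.3%, and for stamen-bearing against pistillate buds 74.0% and 99.4%. False calls made up 4.58%, 4.90% and 4.35% of calls in these simulations. Apart from depth, the simulated libraries differed on average only in the changed rows, with signs drawn at random. No outlying library and no shift in scaling was simulated, so these rates need not hold for the real libraries.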

Results

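The series compared miRNAs of inflorescence buds between sex types of Pistacia chinensis at 2 stages of sex differentiation. Female and male buds came from dioecious plants, and monoecious female and monoecious bisexual buds came from plants that carry more than 1 kind of flower. Each of the 8 combinations of sex type and stage was represented by 1 library, so no group had replicates. The number of reads on miRNA rows was 1159015 in female, 859476 in male, 821235 in monoecious female and 160129 in bisexual buds at stage B. At stage C it was 473553, 419169, 512244 and 492859 in the same order. A count of 3 reads corresponded to 3.77 to 5.55 CPM in 7 libraries and to 18.4 CPM in bisexual buds at stage B.

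The conserved families miR166, miR159 and miR319 held most reads in every library. miR166, which targets HD-ZIP III genes, took 32.2 to 48.6% of reads at stage B and 37.4 to 45.2% at stage C. miR159, which targets GAMYB-like genes, took 30.2 to 37.8% at stage B and 25.3 to 28.4% at stage C. miR319, which targets TCP genes, took 10.7 to 18.1% at stage B and 15.8 to 20.5% at stage C. These shares count reads held by several near-identical rows more than once. With near-identical rows counted once, miR159 took 40.2 to 47.0% at stage B and 34.1 to 36.8% at stage C, and miR166 took 21.4 to 34.8% and 25.4 to 31.6%, below miR159 in 8 of 8 libraries. The 5 most abundant rows were ath-miR159a with 17.1% of all reads and the miR166 rows gma-miR166u, ath-miR166a-3p, zma-miR166h-3p and cpa-miR166e with 7.88 to 9.52% each, of which the last 3 held nearly the same reads. Predicted miRNAs held 1.70 to 4.91% of reads, and 0 rows carried an animal name.

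**Figure D1:**
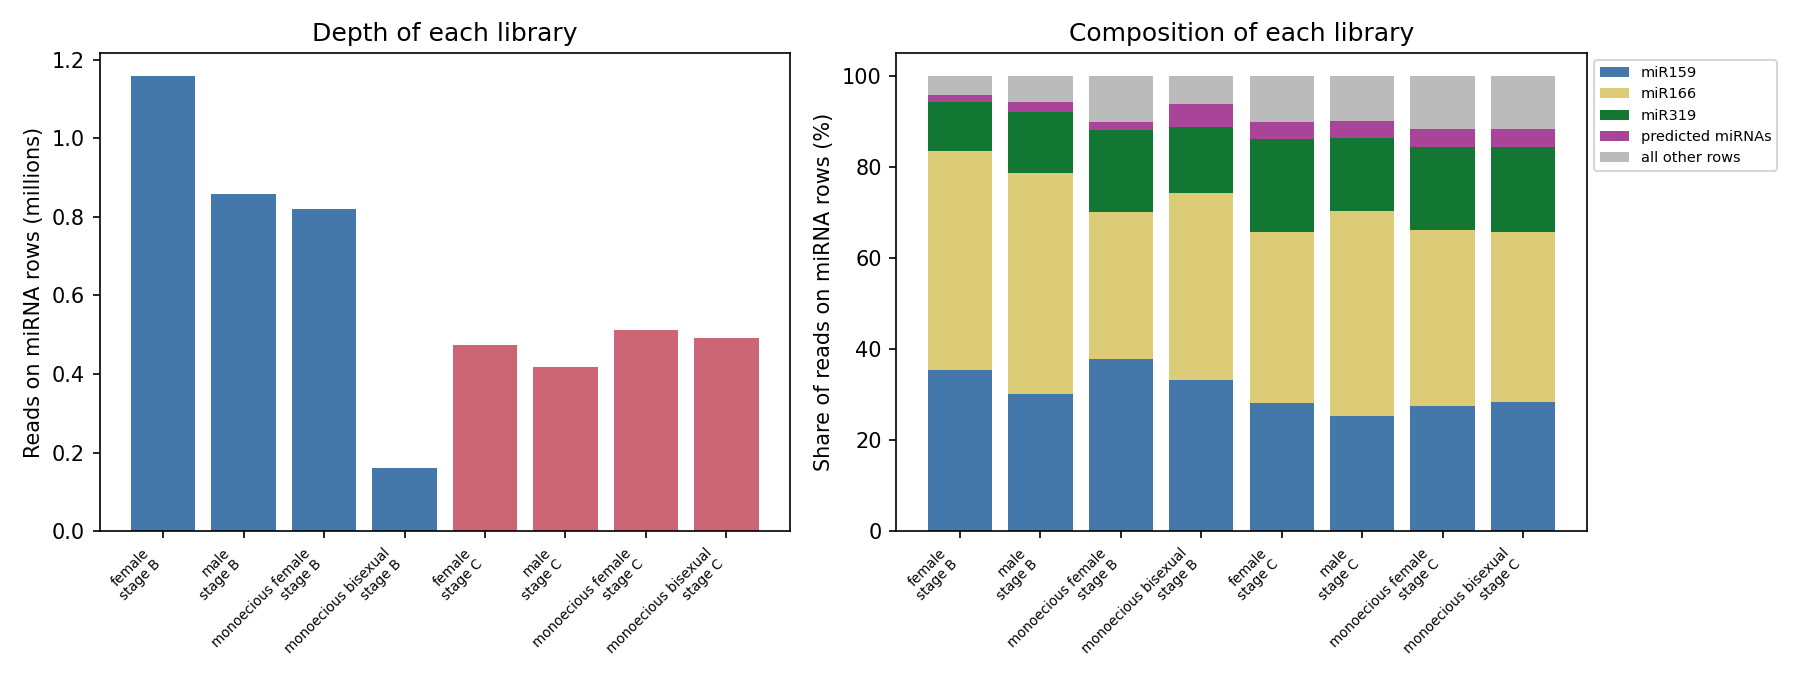
Left, reads on miRNA rows in units of 1000000 for each of the 8 libraries (bars, blue for stage B and red for stage C). Right, share of those reads in percent taken by miR159, miR166, miR319, predicted miRNAs and all other rows, with shared reads counted on each row. The bisexual library at stage B was the smallest with 160129 reads.

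The bisexual library at stage B stood apart from the others. Its rank correlation across miRNA rows was 0.73 to 0.79 with the other stage B libraries, while the other pairs of the same stage had 0.89 to 0.96. With stage C libraries it was 0.70 to 0.73, while the other pairs across stages had 0.76 to 0.85. This library also had the fewest reads, which can lower a rank correlation, and the correlations were not compared after thinning. osa-miR166d-5p, named for the passenger strand of miR166, took 6.06% of its reads (exact binomial 95% interval 5.94 to 6.18%) against 0.0237 to 0.210% in the other 7 libraries. As shares of the library totals, without TMM factors, and with near-identical rows counted once, 9 rows with at least 20 reads there were at least 4 times above every other library. They were osa-miR166d-5p, osa-miR166b-5p, zma-miR396g-5p, osa-miR396a-3p, gma-miR159a-5p, ath-miR8175, pab-miR3711, novel_19 and novel_74, chosen after their values were seen. With TMM factors pab-miR3711, at 386 against at most 137 CPM, was less than 4 times above, and novel_29, at 3035 against at most 615 CPM, was more than 4 times above. gma-miR167i had 0 reads there and 107 to 359 reads in the other libraries.

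**Figure D2:**
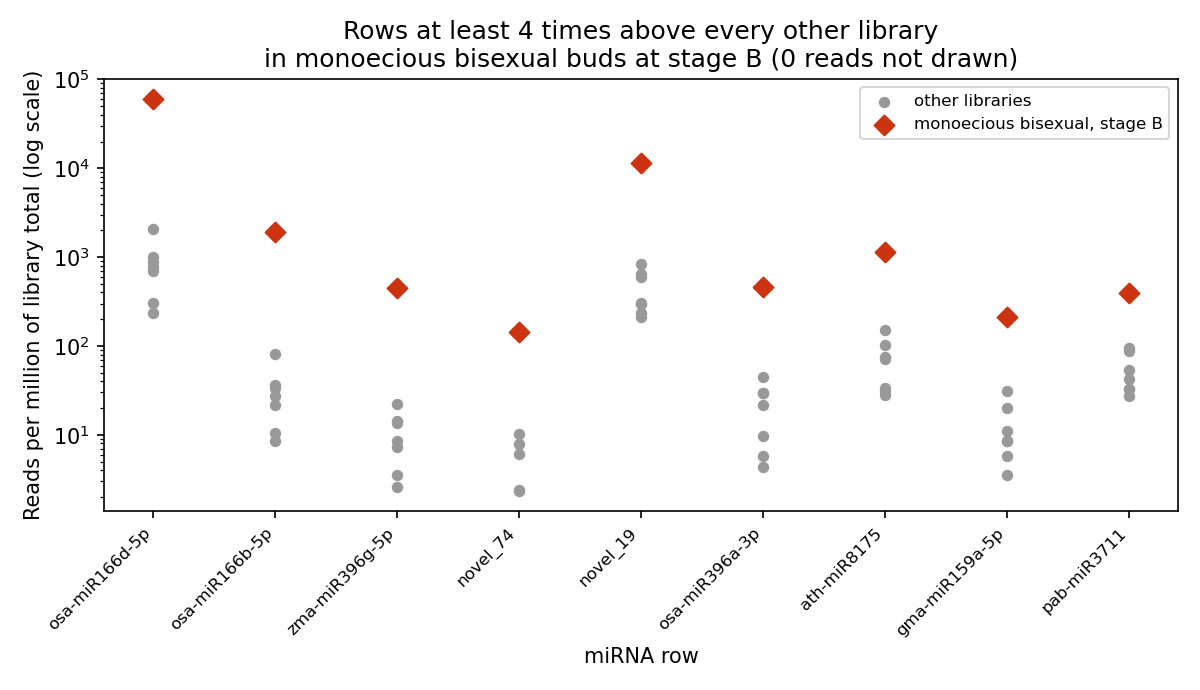
CPM of the library total, without TMM factors, on a log axis for the 9 rows with at least 20 reads that were at least 4 times above every other library in monoecious bisexual buds at stage B (red diamonds). Grey points are the other 7 libraries, and values of 0 reads are not drawn. osa-miR166d-5p was 28.9 times and pab-miR3711 4.18 times above the next library.

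**Figure D3:**
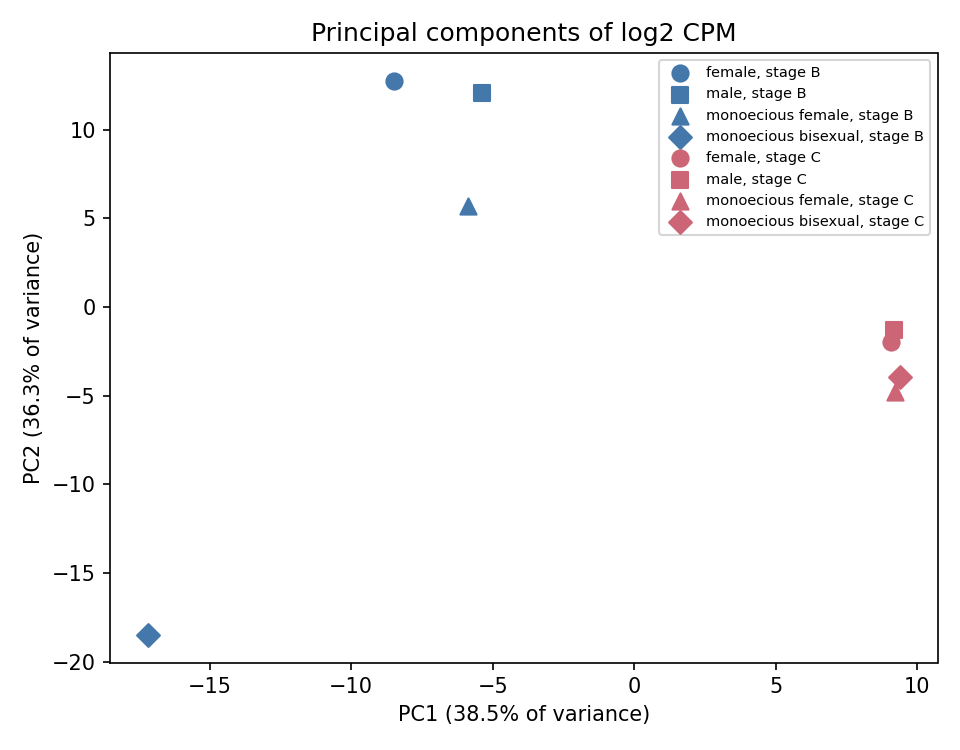
First and second principal components of log2 CPM over miRNA rows, near-identical rows counted once, for the 8 libraries (blue, stage B, red, stage C, marker shape, sex type). PC1 held 38.5% and PC2 36.3% of the variance, and the bisexual stage B library lay at -17.2 and -18.5. That library had the fewest reads, and the components were not computed after thinning.

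The comparison of stage C with stage B asked which miRNAs changed during sex differentiation, and it showed higher miR408, miR398 and miR393 at stage C and lower levels of rows of the abundant miR159. ath-miR408-3p, whose family targets copper proteins such as plantacyanin, rose from 8.44 ± 7.97 CPM at stage B to 175 ± 91.5 CPM at stage C (SD, n = 4 libraries). osa-miR398b, whose family targets copper/zinc superoxide dismutases, rose from 195 ± 99.6 to 1140 ± 428 CPM and was chosen after its values were seen. ata-miR393-5p, whose family targets the TIR1/AFB auxin receptors, rose by 3.68 on the log2 scale (SE 0.65) from 9.96 ± 4.93 CPM. osa-miR159a.1 fell from 78998 ± 12441 to 36245 ± 3789 CPM in TMM-scaled counts (log2 change -1.12), but with total counts alone it had -0.43 and did not pass (adjusted p = 0.0712). Each of these rows moved the same way in 4 of 4 sex types. In all, 31 rows were higher and 16 lower at stage C of 248 tested, which made 22 and 14 groups of near-identical rows.

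In the nutrient and copper list, 2 of 4 tested families rose and 1 fell, and the counts adjusted over the list alone were the same. miR408 rose by 4.24 on the log2 scale (SE 0.87, edgeR adjusted p = 0.00667) and miR398 by 2.51 (SE 0.44, adjusted p = 0.00379). miR399, which targets the PHO2 regulator of phosphate uptake, fell by 1.58 (SE 0.43, adjusted p = 0.0244), but with total counts alone its change was -0.49 and did not pass. The miR395 family, which targets genes of sulphate assimilation, had a change of 0.41 (SE 0.50) that did not pass, while its most abundant row taken alone passed (2.58, adjusted p = 0.00597). Within that family osa-miR395c, named after its value was seen, rose from 17.2 ± 7.99 to 129 ± 38.8 CPM, while ath-miR395a and tae-miR395b, also named after their values were seen, had -1.84 (SE 0.69) and -1.45 (SE 0.81) and did not pass.

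In the auxin list, 1 of 4 families rose, also over the list alone. It was miR393, with a log2 change of 3.05 (SE 0.67, adjusted p = 0.00920). miR390, which triggers trans-acting siRNAs against auxin response factors, had 0.87 (SE 0.50) and did not pass. Its near-identical rows ath-miR390a-3p and gma-miR390a-3p, named after their values were seen, passed at 2.92 and 2.91 (edgeR adjusted p = 0.0119 each). The row ath-miR390a-5p, with more reads, was not called. miR160 and miR167, which target auxin response factors, had -0.40 (SE 0.71) and -0.20 (SE 0.57), did not pass, and changed sign to 0.81 and 0.93 with total counts alone. The most abundant row of miR160 taken alone passed, at -1.99 (adjusted p = 0.0295).

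In the list of floral organ and meristem regulators, 1 of 9 families rose and 1 fell, and 1 rose and 2 fell when adjusted over the list alone. miR169, which targets NF-YA genes, rose by 3.07 (SE 0.56, adjusted p = 0.00379), and it was named after its value was seen. miR159 fell by 1.42 (SE 0.39, adjusted p = 0.0244) but had -0.32 (adjusted p = 0.0614) with total counts alone, and its most abundant row taken alone did not pass (adjusted p = 0.0529). miR166 had -1.17 (SE 0.40) and miR396, which targets growth-regulating factors, -1.11 (SE 0.43), and neither passed over all features. miR319 had -0.71 (SE 0.37), did not pass, and had 0.39 with total counts alone.

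In the NBS-LRR and phasiRNA list, miR482, which targets disease resistance genes, fell by 1.48 (SE 0.46, adjusted p = 0.0462), so that 1 of 2 families fell, also over the list alone. With total counts alone miR482 had -0.38 and did not pass, nor did it with RLE factors (adjusted p = 0.0554), and miR472 went from -1.11 (SE 0.71) to 0.10. In the phase change list, 0 of 3 families passed in either adjustment. miR156, which targets SPL genes, had 0.67 (SE 0.80). Its row ath-miR156a-5p, named after its value was seen, passed at 2.42 (SE 0.67, edgeR adjusted p = 0.0468). The miR156 row gma-miR156z went the other way, from 10, 8, 19 and 0 reads at stage B to 0, 0, 1 and 3 at stage C. miR172, which targets AP2-like genes, had -0.39 (SE 0.41), and miR535 had -0.20 (SE 0.83), and both changed sign with total counts alone, to 0.70 and 0.95. In the silencing list 0 of 2 families passed, with 0.65 (SE 0.41) for miR168, which targets AGO1, and 1.18 (SE 0.60) for miR403, which targets AGO2. The MYB list had 0 of 1 passing, with 0.16 (SE 0.42) for miR858. The anther and pollen list also had 0 of 1, with -0.32 (SE 0.64) for miR845, which became 0.79 with total counts alone. Outside the lists, miR6478, named after its value was seen, rose by 1.55 (SE 0.42, adjusted p = 0.0244).

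The called families had the same direction with total counts alone and without any 1 library, but some calls were lost. Leaving out 1 library at a time gave log2 changes of 1.24 to 5.20 for the 5 families called higher and -1.93 to -1.19 for the 3 called lower, and all 8 stayed called without both bisexual libraries. Total counts alone moved the median change of the 38 named families by 1.11, and the 3 families called lower lost their calls and the 5 called higher kept them. Total counts raised every named family, by 1.03 to 1.37, so the direction of the 5 called higher was fixed. Their kept calls therefore do not test scaling. Without the monoecious female library of stage B none of the 8 families passed, with adjusted p of 0.0519 for miR169, 0.0564 for miR398, 0.0618 for miR393, 0.0843 for miR408, miR482 and miR6478 and 0.142 for miR159 and miR399. Without that of stage C none passed either, with adjusted p of 0.0734 for miR169 and miR398, 0.0790 for miR393 and miR482, 0.121 for miR408 and miR6478, 0.122 for miR399 and 0.188 for miR159. miR159, miR399, miR482 and miR6478 also lost their calls without any 1 of the female and male libraries, with adjusted p of 0.0802 to 0.302, and miR393 without the female stage C library (adjusted p = 0.0545).

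**Figure D4:**
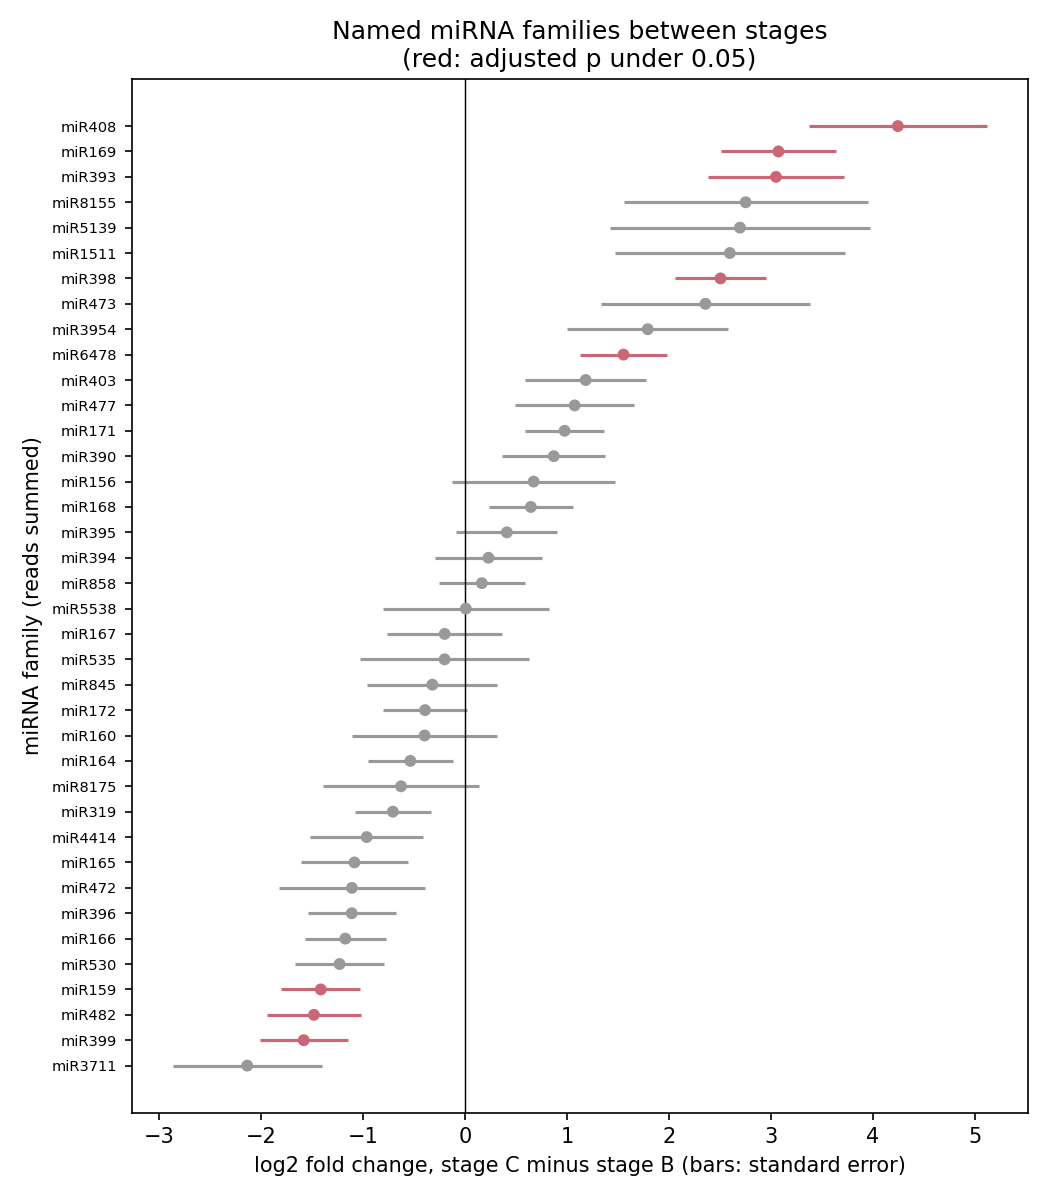
Log2 fold change of stage C minus stage B for 38 named miRNA families with reads summed per family (points) and standard errors (bars). Red marks adjusted p under 0.05 in edgeR, with 5 families higher and 3 lower. With total counts alone the 5 higher families stayed positive, which was fixed since total counts raised every named family. miR319, miR172, miR160, miR167, miR472, miR535 and miR845 then changed sign to positive.

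Among predicted miRNAs, 10 rows rose and 4 fell. Tested together with the summed families, 7 of 58 rose and 5 fell, and 7 rose and 6 fell when adjusted over the list alone. novel_41 went from 2.40 ± 3.04 to 206 ± 160 CPM, novel_39 from 25.1 ± 10.3 to 370 ± 99.7 CPM, novel_100 from 25.6 ± 26.4 to 263 ± 117 CPM and novel_25 from 43.4 ± 37.8 to 509 ± 175 CPM, each higher in 4 of 4 sex types. In novel_41 this rested on 1, 1, 4 and 0 reads at stage B and 4, 107, 248 and 145 reads at stage C in female, male, monoecious female and bisexual buds, so its fitted change depends on the prior count. novel_44 fell from 145 ± 60.2 to 14.6 ± 8.66 CPM and novel_35 fell by 1.91 on the log2 scale (SE 0.37) to 105 ± 22.1 CPM, each in 4 of 4 sex types. novel_30 fell from 196 ± 203 to 41.0 ± 36.0 CPM in 4 of 4 and novel_56 from 77.1 ± 82.1 to 4.31 ± 4.54 CPM in 3 of 4 sex types. With total counts alone novel_35 had -1.22 (adjusted p = 0.0557) and novel_30 -1.27 (adjusted p = 0.145) and did not pass, while novel_44 and novel_56 stayed called.

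Other called rows with large changes were further names of the same families. osa-miR408-3p rose by 4.71 (SE 0.85), and ppt-miR408b, bra-miR408-5p and gma-miR408d, which held nearly the reads of ath-miR408-3p, rose by 4.31 to 4.35. bdi-miR159a-3p, lus-miR159b, ath-miR159b-3p and osa-miR159f fell by 1.63, 1.35, 1.34 and 1.20, and ath-miR399b fell by 1.56. The 5 most abundant rows fell by 0.74 to 0.85 in TMM-scaled counts, with adjusted p between 0.0240 and 0.0465, but with total counts alone they had -0.17 to -0.05 and did not pass (adjusted p between 0.487 and 0.855). The split of calls depended on scaling. With total counts alone 54 rows were higher and 4 lower, with a shift of 0.70 in the median change of all rows, and all 31 rows called higher stayed called while 4 of the 16 called lower did, namely novel_44, novel_56, lus-miR159b and ath-miR159b-3p. Since total counts raised the changes, the kept calls of the 31 rows do not test scaling. Leaving out 1 library of a sex type leaves the stage comparison to the other 3 sex types. The number of calls was 4 without either female, 19 without either male and 0 without either monoecious female library, and 106 or 112 without the bisexual stage B or stage C library.

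No miRNA passed the edgeR test between stamen-bearing and pistillate buds. The comparison of stamen-bearing buds (male and bisexual) with pistillate buds (female and monoecious female) asked for miRNAs tied to stamen development in both sexual systems. edgeR called 0 of 248 rows, with 12 at an unadjusted p under 0.05, and DESeq2 called 3. The rows with the smallest p were novel_60 (log2 change -2.81, SE 0.62), novel_26 (-1.30, SE 0.36), novel_18 (1.19, SE 0.34), novel_36 (-2.94, SE 0.84) and osa-miR399a (-1.09, SE 0.40), with adjusted p between 0.645 and 0.835. DESeq2 passed novel_60, novel_26 and novel_18. No family of any list passed over all features or over its list alone, and miR398 had 0.70 (SE 0.42), miR858 -0.53 (SE 0.42) and miR172 -0.43 (SE 0.41). Without the bisexual stage C library edgeR made 42 calls, with the bisexual level then taken from the stage B library alone.

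Male and female buds of dioecious plants had rank correlations across miRNA rows of 0.96 at stage B and 0.92 at stage C. novel_106 was read in male buds alone, with 21 and 49 reads at stages B and C against 0 in the other 6 libraries. In male against female buds this was at least 8.36-fold at stage B and at least 17.9-fold at stage C. Against bisexual buds it was at least 1.71-fold at stage B, where the bisexual library was shallow, and at least 19.7-fold at stage C. novel_21 was lower in male buds at both stages, with 85.6 against 524 CPM at stage B and 113 against 1432 CPM at stage C. The miR160 row csi-miR160 was 2.03 times (95% interval 1.51 to 2.75) and 2.42 times (1.73 to 3.41) the female level in male buds. The miR160 rows osa-miR160e-5p and ath-miR160a-5p were also higher in male buds at both stages. osa-miR160f-5p, the miR160 row with most reads, went the other way at stage C, at 49.99 CPM in male against 103 CPM in female buds. At stage B it stood at 290 against 245 CPM. The miR171 row osa-miR171b, whose family targets GRAS regulators of meristems, was 2.72 times (2.38 to 3.13) and 2.03 times (1.85 to 2.23) the female level.

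At a ratio of at least 2 at both stages and at least 50 reads, 8 rows were higher and 1 was lower in male buds, or 5 and 1 with near-identical rows counted once. These were csi-miR160, osa-miR171b, novel_102, novel_22 and novel_29, higher, and novel_21, lower, and apart from novel_21 they were chosen after their values were seen. 2 rows, mes-miR477a and nta-miR477a, moved in opposite directions at the 2 stages. edgeR called 0 rows, with 12 at an unadjusted p under 0.05, and DESeq2 called 0. The 5 smallest p belonged to novel_106, novel_36 (log2 change -4.82, SE 1.45), novel_41 (3.82, SE 1.24), novel_21 (-3.30, SE 1.14) and novel_37 (-2.85), all at an adjusted p of 0.908. novel_36 had 0 and 0 reads in male and 3 and 5 reads in female buds, so its fitted change depends on the prior count. Without both bisexual libraries novel_21 passed (-3.22, SE 0.41, adjusted p = 0.0175), and without the bisexual stage C library edgeR made 3 calls. No family of any list passed, with 0.94 (SE 0.90) for miR160 and 0.90 (SE 0.76) for miR167.

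**Figure D5:**
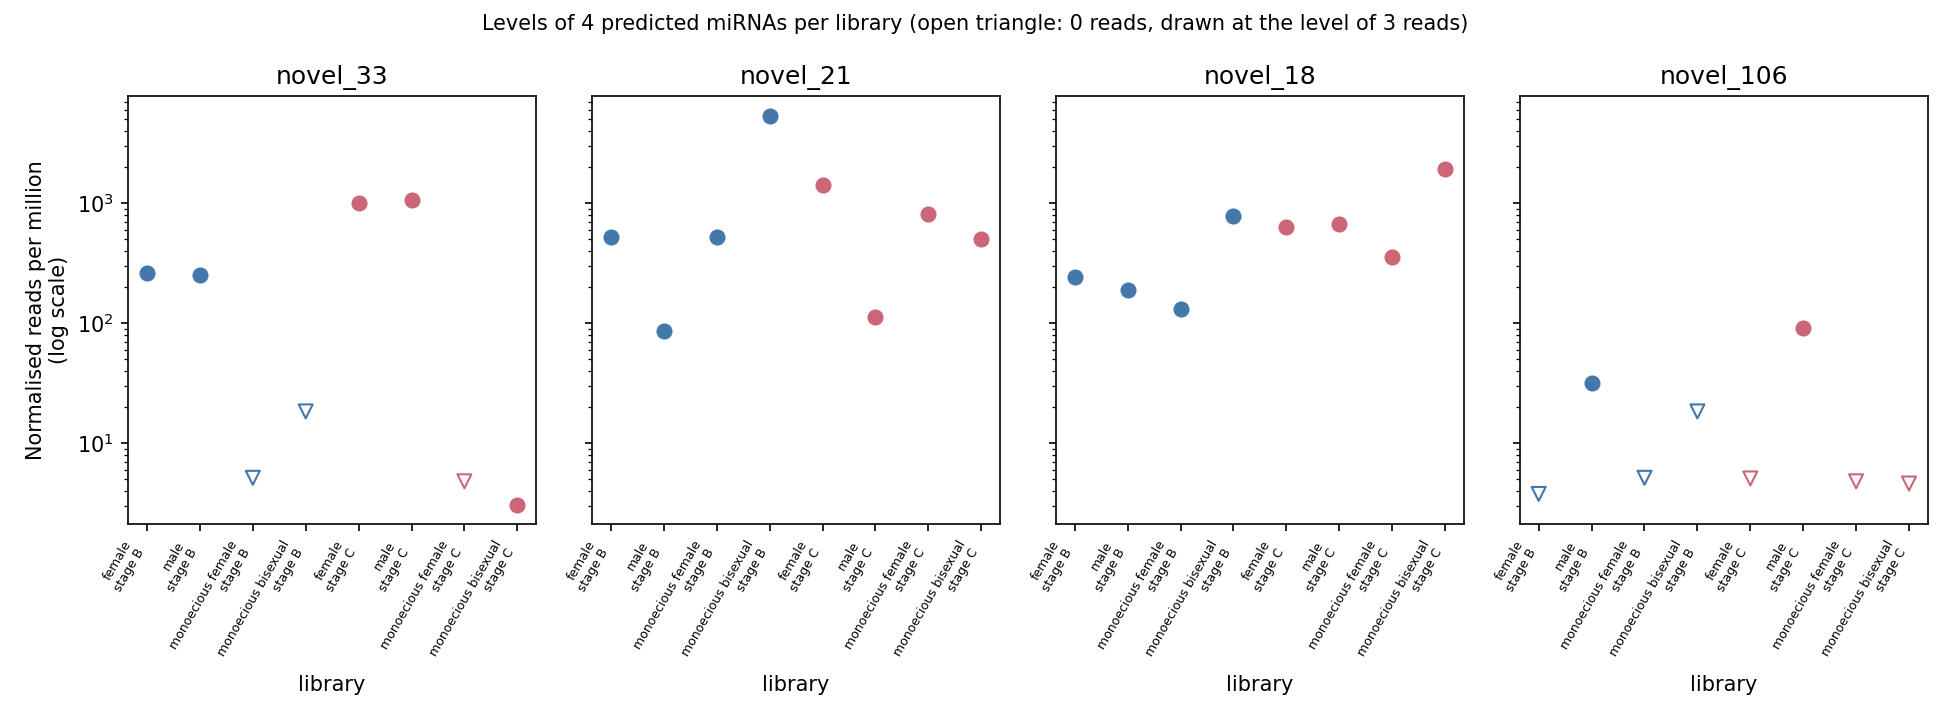
Normalised CPM on a log axis for novel_33, novel_21, novel_18 and novel_106 in each of the 8 libraries (blue, stage B, red, stage C). Open triangles mark 0 reads and are drawn at the level of 3 reads. novel_33 was read in the 4 dioecious libraries and held 0, 0, 0 and 2 reads in the 4 monoecious ones.

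Bisexual and monoecious female buds came from the same strain, so this comparison was not confounded with strain. novel_18 was 5.98 times (95% interval 4.46 to 8.05) the monoecious female level in bisexual buds at stage B and 5.36 times (4.64 to 6.20) at stage C. The miR399 row tcc-miR399e was at 0.143 times the monoecious female level at stage B, from 3 against 75 reads (95% interval 0.0289 to 0.435), and at 0.157 times at stage C (0.0681 to 0.320). The miR399 row osa-miR399a was at 0.278 and 0.228 times that level at the same stages. novel_13 was 0.0559 and 0.391 times and novel_26 0.183 and 0.258 times that level at stages B and C. At a ratio of at least 2 and at least 50 reads, 1 row was higher and 4 were lower at both stages, while 4 moved in opposite directions. With near-identical rows counted once, 3 moved in opposite directions. Agreement between the stages was thus about as common as disagreement. The rows that went opposite ways were of miR167, with gma-miR167i, chosen after its values were seen, at 0 against 232 reads at stage B and 2.15 times the monoecious female level at stage C.

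Across rows the differences at stage B and stage C had a Pearson r of 0.06 (Spearman rho -0.0080) over 102 groups of near-identical rows, which are not independent replicates. The same r was 0.21 (rho -0.029) in bisexual minus male, which also uses the bisexual stage B library that stood apart, 0.46 (rho 0.42) in male minus female and 0.76 (rho 0.36) in monoecious female minus female. In the last of these novel_33, with 0 against 209 and 0 against 598 reads, lay far out at both stages. Pearson r is sensitive to such a row, and r without it was not computed. In bisexual minus monoecious female edgeR called 0 rows, with 19 at an unadjusted p under 0.05. The smallest p belonged to novel_18 (log2 change 2.50, SE 0.50), tcc-miR399e (-2.79, SE 0.67), novel_26 (-2.15, SE 0.53), novel_60 (-3.50, SE 0.96) and osa-miR399a (-2.00, SE 0.59), with adjusted p between 0.385 and 0.531. DESeq2 called 10 rows, of which 6 were among the 9 rows far above every other library in bisexual buds at stage B, and the others were novel_18, novel_13, novel_26 and tcc-miR399e. edgeR called 54 rows without the bisexual stage C library, where the bisexual arm is the stage B library that stood apart, alone. No family of any list passed, with 1.01 (SE 0.60) for miR398 and -1.22 (SE 0.60) for miR399.

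Monoecious and dioecious buds differed in novel_33. It stood at 263 and 1012 CPM in female and 251 and 1063 CPM in male buds at stages B and C, and its reads in monoecious buds were 0 and 0 in monoecious female buds and 0 and 2 in bisexual buds. Female buds were at least 51.1-fold above monoecious female buds at stage B and at least 210-fold at stage C. Male buds were at least 13.6-fold above bisexual buds at stage B, and at stage C the bisexual level was 0.00289 times the male level (95% interval 0.000349 to 0.0105). The row was called in the pooled comparison (edgeR adjusted p = 0.00166), in monoecious female minus female (adjusted p = 0.00820) and in bisexual minus male (adjusted p = 0.0196), lower in both monoecious libraries of each stage. It was the only row of 248 that edgeR called in each, with 27, 11 and 28 rows at an unadjusted p under 0.05. DESeq2 called 11, 3 and 18 rows, and 5 of the 18 were among the 9 rows far above every other library in bisexual buds at stage B. Sexual system and strain were confounded in all of these.

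Monoecious female buds also held more novel_30 than female buds, at 7.74 times (95% interval 5.16 to 12.02) at stage B and 12.8 times (4.72 to 48.6) at stage C. novel_13 was 3.29 and 2.30 times, novel_25 3.24 and 2.08 times and novel_102 2.73 and 2.19 times the female level, so that 4 rows were higher and 1, novel_33, lower at both stages, and those other than novel_33 were chosen after their values were seen. Without both bisexual libraries edgeR passed novel_30, novel_33, novel_41 and novel_56, named after their values were seen. Bisexual against male buds had 6 rows higher and 3 lower at both stages. mdm-miR396a was 3.99 and 2.26 times, osa-miR398b 2.50 and 2.74 times, ptc-miR6478 3.48 and 2.31 times, novel_118 13.3 and 2.21 times, novel_18 4.12 and 2.84 times and novel_21 62.5 and 4.43 times the male level, and novel_13, novel_26 and novel_33 were lower. The 4 rows novel_24, novel_29, osa-miR159c and osa-miR166d-5p moved in opposite directions at the 2 stages. All but novel_33 were chosen after their values were seen. Tested together with the summed families, 1 predicted miRNA was higher (novel_30, 2.47, SE 0.54, adjusted p = 0.0308) and 2 were lower (novel_33 and novel_56) in the pooled comparison, the same counts as when adjusted over the list alone. In bisexual minus male 1 was lower, and 1 higher and 2 lower when adjusted over the list alone. No named family passed in the pooled comparison or in either part, where miR166 had -0.87 (SE 0.40), -0.84 (SE 0.56) and -0.91 (SE 0.55). The call of novel_33 was lost in monoecious female minus female without either monoecious female library or the female stage C library, with adjusted p up to 0.171. The fitted log2 change, which depends on the prior count, was then -12.23 to -10.20 against -11.56 with 8 libraries, so that the call was lost with fewer libraries and a larger standard error (1.48 to 1.67 against 1.05). In bisexual minus male it was lost without either female library or the male stage C library, with adjusted p up to 0.0794 and changes of -8.43 to -8.32 against -8.40. Without the bisexual stage C library edgeR made 31 calls in the pooled comparison and 59 in bisexual minus male, where the bisexual arm is then the stage B library alone. Without the bisexual stage B library it made 3 in the pooled comparison, and without either bisexual library 4 in monoecious female minus female.

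Whether the difference between stamen-bearing and pistillate buds depended on the sexual system was tested as an interaction, and edgeR called 0 of 248 rows, with 16 at an unadjusted p under 0.05. The smallest p belonged to tcc-miR399e (log2 difference -3.55, SE 0.88), novel_18 (2.62, SE 0.68), novel_21 (5.41, SE 1.59), novel_13 (-3.39, SE 1.03) and novel_41 (-4.85, SE 1.53), all at an adjusted p of 0.684. DESeq2 called 2 rows, novel_18 and novel_21, and edgeR made 28 calls without the bisexual stage C library, again with the stage B library alone as the bisexual arm. Over 207 groups of near-identical rows, male minus female and bisexual minus monoecious female changes had a Pearson r of 0.06 and a Spearman rho of 0.09, and 56.0% had the same sign. These 2 comparisons shared no library.

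Whether the stage change differed between stamen-bearing and pistillate buds was also tested, and edgeR called 0 of 248 rows, with 2 at an unadjusted p under 0.05, and DESeq2 called 0. The smallest p belonged to tae-miR395b (log2 difference 3.24, SE 1.13), csi-miR473 (-5.14, SE 1.98), ahy-miR398 (3.44, SE 1.52), mes-miR477d (-3.34, SE 1.51) and ath-miR398a-3p (3.37, SE 1.53), all at an adjusted p of 1. No family of any list passed, with 2.21 (SE 1.33) for miR160 and 1.82 (SE 0.998) for miR167. Leaving out either male library leaves the stamen-bearing stage change to the bisexual libraries alone, of which that of stage B stood apart. Calls of those fits therefore say nothing about male buds.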

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

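The tests of the bisexual stage B library, of scaling and depth in the stage comparison and of novel_33 were chosen after the results were seen, as were the splits for the interaction results, while the splits for stage, flower class and sexual system and the stage assignments within sex types were set before their outcome was seen. The test of scaling replaced an earlier one whose outcome was fixed for the rows called higher, since total counts raise every change.

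Library measures were compared among the 4 libraries of each stage, and 7 of 16 such sets had a library far from the other 3. The measures chosen after their values were seen gave 3 of 4 and the other measures 4 of 12, where chance gives about 1 in 20 for a single set. Measures of the same libraries are not independent, and the shares counted reads held by several near-identical rows more than once. The bisexual stage B library had 261 rows with reads against 330 to 342, 4.91% of reads on predicted miRNAs against 1.70 to 2.22%, 6.26% on miR166 rows named 5p against 0.0247 to 0.0734%, and a ratio of osa-miR166m to ath-miR166a-3p of 0.0685 against 0.340 to 0.393. The last 2 measures were those chosen after their values were seen. The number of rows with reads also depends on depth, which was lowest in this library, and it was not compared after thinning. At stage C the male library had 45.2% of reads on miR166 against 37.4 to 38.6% and 0.219% on miR166 rows named 5p against 0.0802 to 0.103%, and the female library had 3.61% on predicted miRNAs against 3.90 to 3.94%. With near-identical rows counted once, the male stage C library had 31.6% on miR166 against 25.4 to 26.6%. Predicted miRNAs then took 6.17% against 2.23 to 2.95% in the bisexual stage B library, and 4.63% against 5.10 to 5.28% in the female stage C library. Relative to the spread of its set each gap was then smaller, so these sets may not hold a far library. The count of far libraries was not remade this way.

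The bisexual stage B library also held 9 rows with at least 20 reads that were at least 4 times above every other library, as shares of the library totals. Low depth alone is argued against, since the other 7 libraries, each thinned 50 times to the same number of reads, reached at most 2 such rows. Without the miR166 5p rows 7 such rows remained, but this outcome was fixed, since leaving out rows that take many reads raises the shares of the others. Reads taken by an abundant row lower the shares of all other rows, here by a factor of 1.08. This argues against 1 abundant row taking the reads as the reason why these 7 rows lay above the other libraries. A difference in which read ends or strands were kept is a candidate explanation, since 17 of 44 ratios of a row to the top row of its family lay over 2-fold outside the range of the other libraries, against at most 2 in any other library after thinning. These ratios are not independent, since those of a family share its top row. They include osa-miR166d-5p, osa-miR166b-5p, osa-miR166m and gma-miR167i, which had been seen to stand out. A change in the levels of family members would also move such ratios, so the count does not single out read ends or strands. The biology of bisexual buds at this stage stays open and was not tested, because there is 1 such library.

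In the stage comparison, all 31 rows called higher exceeded the 0.70 log2 shift between TMM and total counts by over 2 standard errors. For rows with large standard errors this outcome was fixed, since being called already required a change of several standard errors. The median SE was 0.54 in these rows and 0.25 in the rows called lower. The test therefore does not decide whether a shift in scaling caused the 31 increases. All 31 stayed called with RLE factors. For the 16 rows called lower, a shift in scaling cannot be told apart from a real decrease, since 9 of 16 exceeded the shift that far. Their median log2 change went from -1.27 (median SE 0.25) to -0.58 (median SE 0.25) with total counts, 0 of 16 changed sign and 4 stayed called, because the shift moved their changes toward 0 while their standard errors stayed the same size. A difference in depth is argued against, since 37 calls were kept after thinning every library to the same number of reads.

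For the split by stage without a sex type term, there were 52 calls in the real split, the highest other had 1, and 1 of 35 splits was as large. That share is under 0.05, but it is the smallest that 35 splits can give. These splits leave out the sex type term of the reported model, so they do not exclude chance for that model. Within sex types there are 8 assignments of stage, too few for a share under 0.05, with 47 calls in the real one and 0 in the highest other.

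For the split by sexual system, with 1 call in the real split, 2 of 35 splits were as large, the real one and the stage split with 52, which is the highest, and the others gave 0. The share of splits is not under 0.05, so this count alone does not exclude chance. For flower class, for the interaction of flower class and system and for the interaction of stage and flower class, the real splits gave 0 calls, so 35 of 35 were as large whatever the other splits gave, and this says nothing about chance. The highest other, with 52, was the split by stage.

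novel_33 was nearly missing in monoecious buds. Low depth is argued against, since 1500 reads were expected in the 4 monoecious libraries at the dioecious share and 2 were counted (exact Poisson 95% interval 0.242 to 7.22). A variant of strain T2 at the locus cannot be told apart from an effect of the sexual system, since the monoecious libraries come from 1 strain.

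For tcc-miR399e, novel_13 and novel_41, male buds were above female buds and bisexual below monoecious female buds at both stages. In novel_41 at stage B this rests on 1 read each in male and female buds and on 0 against 4 reads in monoecious buds. This pattern of directions was not tested by itself. The edgeR interaction, at log2 differences of -3.55, -3.39 and -4.85, did not pass for any of them (adjusted p = 0.684).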

How the results depend on the processing

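The added alternatives (near-identical rows once, most abundant row per family, thinning, both bisexual libraries left out) were chosen after the data were seen. The stage comparison made 43 to 68 calls against 47 under RLE, total counts, either filter, DESeq2 and identical rows once, 34 with near-identical rows once, 41 after thinning and 52 without the sex type term. It made 20 with family sums and 21 with the most abundant row per family, where 96 features were tested, and 108 without both bisexual libraries, where all 47 remained. Leaving out 1 library gave 0 to 112 calls.

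Of the sex comparisons, DESeq2 gave 3 calls for stamen-bearing minus pistillate, 11 for monoecious minus dioecious, 2 for the difference of the stamen effect, 10 for bisexual minus monoecious female, 3 for monoecious female minus female and 18 for bisexual minus male. Monoecious minus dioecious had 3 with a minimum of 50 reads, with family sums and with the most abundant row, and 2 after thinning and without the interaction term. Without both bisexual libraries male minus female had 1 and monoecious female minus female 4. Leaving out 1 library gave 0 to 42 calls for stamen-bearing minus pistillate, 1 to 31 for monoecious minus dioecious, 0 to 28 for the difference of the stamen effect, 0 to 3 for male minus female, 0 to 54 for bisexual minus monoecious female, 0 to 4 for monoecious female minus female, 0 to 59 for bisexual minus male and 0 to 63 for the difference of the stage effect. The highest count for the difference of the stage effect came without a male library, where the stamen-bearing stage change rests on the bisexual libraries alone. The cause of these changes was not tested. Differences at both stages at a 3-fold ratio numbered 1 in male minus female, 4 in bisexual minus monoecious female, 2 in monoecious female minus female and 3 in bisexual minus male. With 10 reads they numbered 14 in male minus female, 18 in monoecious female minus female, 15 in bisexual minus male and 11 in bisexual minus monoecious female. Rows that moved in opposite directions with 10 reads numbered 6, 3, 12 and 12 in the same order.

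Of single rows and families, 1036 values kept direction and side of the threshold, 177 lost and 70 gained the call, and 30 changed sign, all in families that did not pass. With total counts alone the log2 change became 0.81 for miR160, 0.93 for miR167, 0.70 for miR172, 0.39 for miR319, 0.10 for miR472, 0.95 for miR535 and 0.79 for miR845, as total counts moved the median family by 1.11. With a minimum of 50 reads miR160 had 0.21, miR167 0.34 and miR172 0.12, and after thinning miR160 had 0.10 and miR167 0.20. DESeq2 gave 0.088 for miR535 and the most abundant row 0.15 for miR845. Without both bisexual libraries miR156 had -0.0018 and miR858 -0.18. Leaving out 1 library gave -0.12 to 1.22 for miR156, -1.29 to 0.014 for miR160, -0.93 to 0.27 for miR167, -0.023 to 0.72 for miR395, -0.90 to 0.53 for miR535, -0.69 to 0.047 for miR845 and -0.31 to 0.44 for miR858. The cause was not tested for the other settings. The planned pseudocounts were not run, since the table holds counts. Depth limits the bisexual stage B library most, where 3 reads are 18.4 CPM.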

Other observations

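Without both bisexual libraries, a setting chosen after the data were seen, 14 of 38 named families were higher and 12 lower at stage C in edgeR, and all 8 families called with 8 libraries stayed called. The 14 include miR1511, miR5139 and miR8155, which had similar counts. miR396 then had -1.48 (SE 0.31, adjusted p = 0.000324), miR166 -1.43 (SE 0.34, adjusted p = 0.00128) and miR403 1.79 (SE 0.40, adjusted p = 0.000599). With 8 libraries and total counts alone miR396 had -0.01 and miR166 -0.08, and scaling was not varied with 6 libraries, which still confound sex type with strain.

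Rows of different families had similar counts. rgl-miR5139, cpa-miR8155 and ppe-miR1511-3p held 21 reads each in female buds at stage C, 28 each in monoecious female buds and 21 each in bisexual buds at stage C. In male buds at stage C they held 28, 26 and 26 reads. They held 0 to 2 reads in female, male and monoecious female buds at stage B, and 18, 13 and 13 in bisexual buds at stage B. Whether these 3 rows share reads was not tested, since no sequences were used here.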
